A study of Mus musculus with 8 samples.

How the data were processed

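Total RNA from mouse liver was labelled as biotinylated cRNA and hybridized to Illumina mouse bead arrays, per the labels' protocols. The deposited tables hold 2 versions of the same 8 arrays. The first gives 1 signal intensity per probe, named raw signal per the file headers. The second is a deposited value table of linear intensity. BeadStudio is named in the submitters' processing notes with no version. No detection p, no negative control probes, no bead counts and no chip are given, and the labels state neither the background treatment nor the normalization.

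The deposited intensities were checked before use. Both arrays of week 1 hold no signal at or below 0, with minima of 66.4 and 71.3, whereas the 6 arrays of weeks 2, 4 and 6 each hold 34 to 8049 such probes. A background had therefore been subtracted in those 6 arrays and not at week 1. The deposited value table is a straight line of the raw signal on 6 arrays, with slopes of 0.92 to 1.61 and largest residuals of 0.006 to 0.013. On the infected arrays of weeks 4 and 6 the largest residuals were 331 and 75.4. On these 2 arrays 56.0% and 54.4% of the raw signals and 51.4% and 50.1% of the value table carry over 7 digits, mostly ending in 5, as means of 2 values do, and on the other 6 none do. These 2 arrays may thus be means of 2 hybridizations, which the labels do not state. Medians of the value table were 72.9 to 126 across arrays. It is linear and not centred, and how its scale was set is not stated.

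The design fixed before the data were examined called for normexp background correction from detection p values (neqc), which the tables do not allow. In its place, the background of each array was taken from its own signals. Its mean is the peak of the density of signals below the 75th percentile, and its SD the root mean square distance of the probes below the peak. Limma's saddle-point estimate was not used because it put the background near the lowest probe and would have called 24280 to 24494 probes detected per array. Signals were corrected with the normexp model, quantile normalized with an offset of 16 and put on a log2 scale (limma 3.58.1 in R 4.3.3). A probe was called detected where its signal lay above the background with a one-sided normal p under 0.01. Background SDs were 4.08 to 9.83 and 11583 to 13417 probes were detected per array. Probes detected on at least 2 arrays were kept, 14601 of 24613. Matched random lists were drawn with matrixStats 1.5.0, and tables were read with the data.table package (version 1.17.8). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

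Probes were named from the platform annotation given with the data, updated through Entrez numbers in a RefSeq gene table of assembly GRCm38.p6. One gene symbol was given for 20984 probes, several for 1 and none for 3628. Of the named probes, 20968 were found in the gene table and 16 kept the name of the annotation. For each symbol the kept probe with the highest mean over the 8 arrays was used, which left 10380 genes. Of them 1922 had over 1 kept probe. Among 261 named genes, 47 had another kept probe, and in 10 of these a second probe had the opposite sign at the week of the largest difference. The genome build of the array design is not given, so no coordinates are stated.

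Arrays were grouped by infection and by week, with 1 array per group and week. For infection across weeks, limma's lmFit and eBayes were fitted to all 8 arrays with the week as 4 levels, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The labels give the same weeks to both groups, so each week pairs 1 infected with 1 uninfected array. As a check, the deviations from the group means correlated across genes at 0.57, 0.35, 0.31 and 0.41 within weeks 1, 2, 4 and 6. The infected array of week 4 correlated best with the uninfected array of another week, at 0.35. The late against early contrast was the mean difference at weeks 4 and 6 minus that at weeks 1 and 2, and the slope per week in uninfected mice came from a fit with separate lines for both groups. At a single week no test was possible, so differences and counts at 2-fold or more among genes detected on at least 1 array of the week are given beside the same counts between uninfected arrays. Those uninfected pairs also differ in week, which the 2 arrays of a week share. A count or list median within their spread therefore does not show that infection had no effect. Where a gene was below background on one array, the fold is a lower bound, taken against the higher of its own signal and the lowest detected signal of that array.

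Gene lists, 34 in number with at least 5 measured members each, were written before the data were examined. They were tested across weeks with camera (correlation 0.01), camera with an estimated correlation and fry, adjusted over lists. At each week the median difference of a list was placed among 10000 random lists of the same size, drawn from 20 bins of mean signal. Such a percentile describes these arrays and is no p value. Some genes belong to 2 lists, such as Lcn2 in the acute phase and oncofetal lists.

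Genes were named by a rule fixed in advance. Across weeks, late against early and for the slope, the genes past the threshold with the largest differences (12, 8 and 5 per direction) were to be named, and where fewer than 5 passed in a direction, the 10 with the smallest p. At each week the 6 highest and 6 lowest were named, with bounds ranked as such. In each list up to 4 members with the largest mean difference and up to 4 at the week of the largest median were available.

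The fits were tested on simulated data made from each gene's fitted values and residual SD, with 100 genes changed by 1 log2 unit and 100 by 2. The list tests were run on a simulated list of changed genes, and the background step on simulated arrays. The alternatives were no normexp correction, scaling to the same median, cyclic loess, the deposited value table, an offset of 50, no filter and a filter on all 8 arrays, eBayes with trend and robust settings, no week in the fit, the week as a straight line, every probe tested, 1.5-fold in place of 2-fold, the mean of the 4 uninfected arrays as the reference, and leaving out each week. The saddle-point background, the uninfected arrays of weeks 2 and 6 as reference for week 4, week 1 without the members of the pancreas, gut and adipose lists, and an estimated correlation without week 1 were added after the data were seen. The chip could not be used as a block because none is named.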

Results

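Gene expression was measured in whole liver of male mice of the inbred FVB/N strain with Illumina mouse bead arrays, on which biotin-labelled RNA copies bind to probes carried on beads. Infected mice had received 15 metacercariae of Clonorchis sinensis by mouth at 6 weeks of age. Metacercariae are the encysted larvae of this liver fluke, which settles in the bile ducts. Livers were taken 1, 2, 4 and 6 weeks later, with 1 array of infected and 1 array of uninfected liver at each week, 8 arrays in all. The labels do not say how many mice an array stands for. Each array held 24613 probes, and 11583 to 13417 of them (47.1% to 54.5%) lay above the array's background. After probes were joined into genes, 10380 genes were tested. With 1 array per group at a week, the values of a single week have no replicate error, and the number of arrays limits their precision. Folds are ratios of normalized signal plus an offset of 16, which makes folds of dim genes smaller.

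The first comparison asks how infected liver differed from uninfected liver at each week. At week 1 the infected liver carried far more RNA of genes listed for neutrophils, the white blood cells that arrive first at inflamed tissue. Arrays of whole liver do not show which cells, mature or precursor, made this RNA. All 11 measured genes of the neutrophil list were at least 2-fold higher, with a median log2 difference of 5.10, above all 10000 random lists of matched signal (5.04 with genes below background on one array at their bound, and 3.51 to 4.68 under 6 other background and scaling settings). S100a9 was 132-fold higher and S100a8 120-fold higher. These encode the subunits of calprotectin, an abundant neutrophil protein. Camp, a granule antimicrobial peptide, was 83.3-fold higher, Ltf (lactoferrin) at least 125-fold and Mpo (myeloperoxidase) at least 33.0-fold. Lcn2, an iron-binding acute phase protein that neutrophils also store, was 133-fold higher, and Cd14, a receptor for bacterial lipopolysaccharide, was 49.8-fold higher.

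Other immune and tissue repair genes were higher in the same array. Of 23 measured macrophage and Kupffer cell genes, 18 were at least 2-fold higher and none were lower by as much (median 1.52, and 1.32 with bounds), with Gpnmb at least 9.83-fold and Lyz2, which encodes lysozyme, 8.97-fold higher. A second Lyz2 probe differed by only 0.14 on the log2 scale and a second Gpnmb probe by 1.75. Of 10 MHC class II genes, which present antigen to T cells, 6 were at least 2-fold higher (median 1.77, and 1.65 with bounds), among them Cd74 (4.60-fold) and H2-DMb1 (6.43-fold). The list of the type 2 response, the arm of immunity raised against worms, had 8 of 16 genes at least 2-fold higher (median 0.94). Chil4, a chitinase-like protein of alternatively activated macrophages, was at least 32.5-fold higher, Ccl24, which attracts eosinophils, 19.7-fold and Mgl2 12.5-fold. Second probes of Chil4 and Mgl2 were higher by 1.29 and 2.23 on the log2 scale. In the list of eosinophils, mast cells and basophils, the eosinophil granule genes Prg2 (13.7-fold) and Ear3 (at least 12.1-fold) were higher, while the list's median was 0.28 over 6 genes. Of 20 inflammatory cytokine and chemokine genes, 14 were at least 2-fold higher (median 1.58), with Cxcl14 at least 18.0-fold (2.65 on the log2 scale by a second probe) and Il1b 7.62-fold. The interferon gamma list had a median of 0.73, led by Ubd, a ubiquitin-like protein, at 26.7-fold. The type I interferon list had a median of 0.32 and 1 of 13 genes at least 2-fold higher. T cell genes had a median of 0.47 (0.21 with bounds), B and plasma cell genes of 0.49, and NK and cytotoxic cell genes of 0.33.

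Of 31 fibrosis and matrix genes, 18 were at least 2-fold higher at week 1 and none were lower by as much (median 1.64). Col1a1, a chain of type I collagen, was 22.9-fold higher, Timp1, an inhibitor of matrix proteases, 20.5-fold and Acta2, the smooth muscle actin of activated stellate cells, 6.34-fold (1.22 on the log2 scale by a second probe). Of 16 bile duct genes, 8 were at least 2-fold higher and 1, Tff2, was lower by as much, at -2.34 on the log2 scale (median of the list 1.06). The higher ones included the keratin gene Krt7 (4.34-fold) and Prom1 (measured at 7.75-fold, at least 7.5-fold). Cell cycle genes were at least 2-fold higher in 17 of 27 cases (median 1.2). They included Mcm5, part of the helicase that opens DNA for replication (9.74-fold), and Cdkn1a, an inhibitor of the cycle (6.23-fold). Immediate early genes had 8 of 15 members at least 2-fold higher (median 1.39, and 0.71 with bounds), led by Gadd45g (13.7-fold) and Socs3 (10.5-fold), and oncofetal and regeneration genes 12 of 22 (median 1.68, and 1.18 with bounds), with Lgals3 (14.1-fold) and Ly6d (15.7-fold) after Lcn2. Acute phase genes had 7 of 29 (median 0.49), with Saa2 47.6-fold and Saa1 15.0-fold higher. Saa1 and Saa2 are close copies of each other, and their probes cannot be taken as independent.

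Several lists of hepatocyte metabolism were lower at week 1, although cholesterol synthesis was not (median 0.27, under the 0.37 to 0.80 between pairs of uninfected arrays of weeks 2, 4 and 6) and glutathione and oxidative stress defence differed little (median -0.02). Fatty acid oxidation had a median of -0.41, below all 10000 random lists, with Cyp4a10, a target of the lipid sensor PPAR alpha, 4.37-fold lower and Ehhadh 2.36-fold lower. Cytochrome P450 drug metabolism had a median of -0.30 (Cyp2c29 4.40-fold and Cyp2c54 4.30-fold lower, although a second Cyp2c29 probe differed by only -0.06). Gluconeogenesis and fasting had a median of -0.47, with G6pc, the last enzyme of glucose release, 3.39-fold lower, and bile acid synthesis and transport of -0.28, with the sterol transporter gene Abcg8 3.65-fold lower. The medians of the gluconeogenesis and bile acid lists lay within the 0.10 to 0.76 and 0.06 to 0.39 seen between the same pairs. Hepatocyte secretory proteins differed little (median -0.08), and endothelial genes likewise (median 0.12).

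The uninfected array of week 1 held RNA of neighbouring tissue. Of 19 exocrine pancreas genes, 18 were at least 2-fold higher in it (median -6.58 for infected minus uninfected). The pancreas genes Clps (238-fold), Ctrb1 (205-fold), Pnliprp1 (173-fold), Cpa1 (161-fold), Reg1 (129-fold) and Cpb1 (127-fold) were the 6 most lowered genes in infected liver. In all, 587 genes were at least 2-fold higher and 204 at least 2-fold lower at week 1. The count of lower genes was 184 without the members of the pancreas, gut and adipose lists, 66 in the deposited value table and 644 against the mean of the 4 uninfected arrays. Only listed genes were left out, so other genes of neighbouring tissue may remain among the 184. The deposited value table keeps a floor under all signals, which shrinks folds of dim genes. The count of 644 also carries the differences in background treatment and probes between week 1 and the later arrays. Against that mean the log2 differences of the 6 pancreas genes were -1.56 to -0.87. The uninfected array of week 1 is part of the mean and carries this sign. The pancreas list had a mean log2 signal of 12.17 in it, 6.47 in the infected array of week 1 and 5.95 to 6.21 in the later uninfected arrays. Pairs of uninfected arrays with week 1 on one side differed at least 2-fold in 1365 to 2216 genes, more than the 791 of week 1. Those pairs cross weeks and background treatments, which the 2 arrays of week 1 share, so they are no yardstick for infection.

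**Figure D1:**
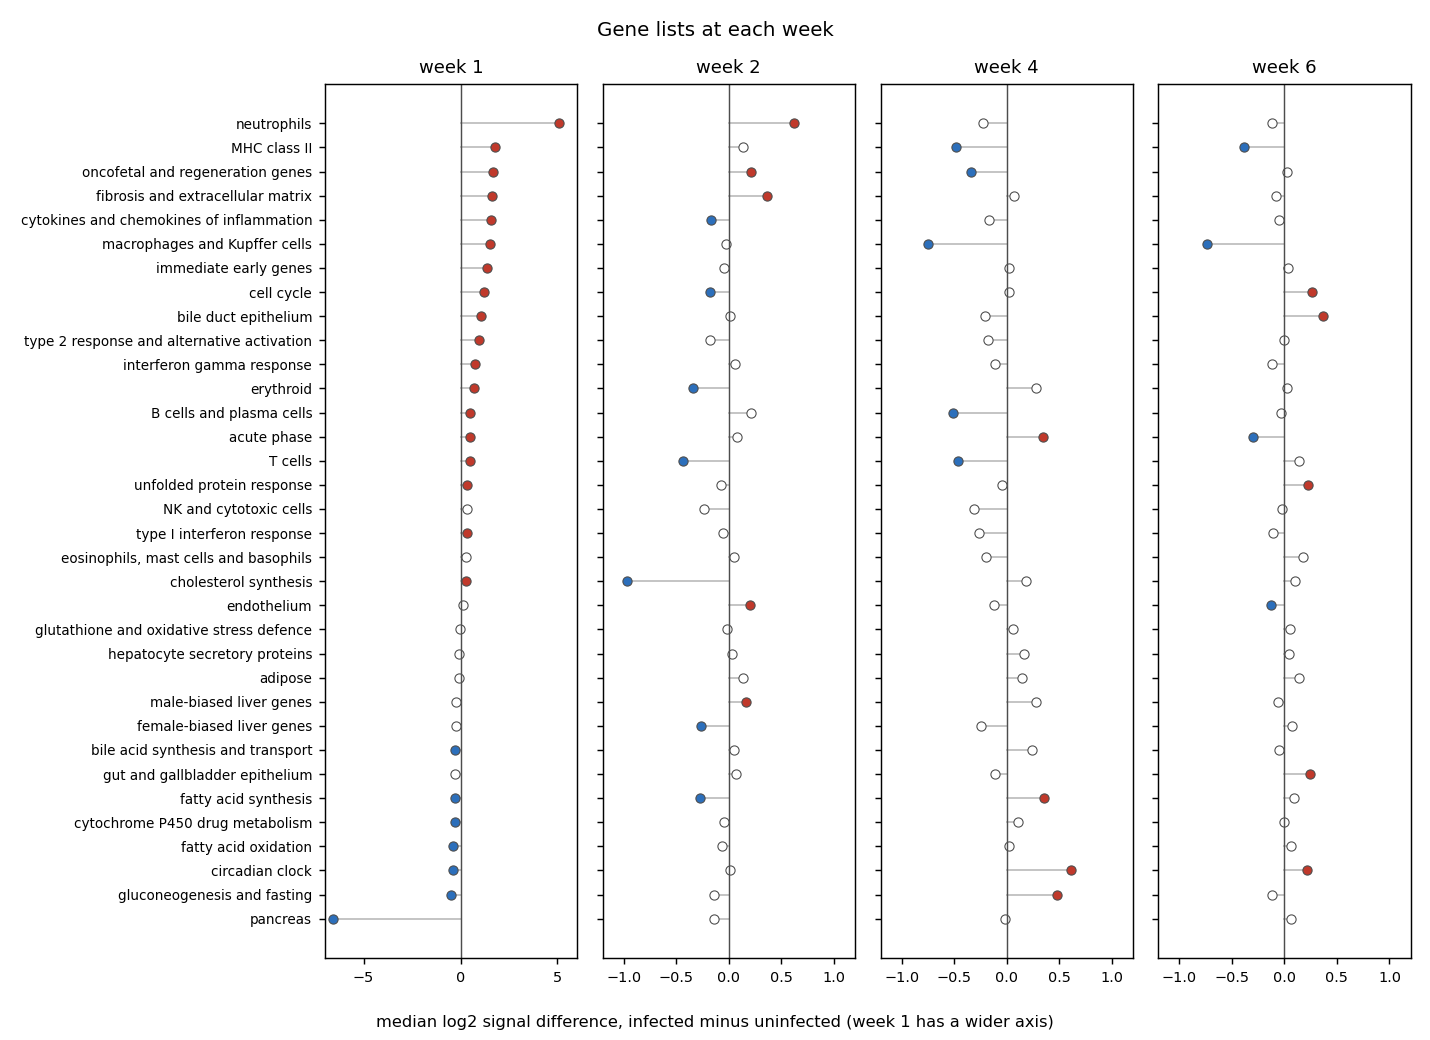
Median log2 difference in signal, infected minus uninfected, for 34 gene lists (rows) at each week (panels, with a wider axis at week 1). Each point is 1 list, filled red (higher) or blue (lower) where the median lay outside the middle 95% of 10000 random lists and open otherwise. Neutrophil genes lie at 5.10 and pancreas genes at -6.58 at week 1, cholesterol synthesis at -0.97 at week 2, and macrophage genes at -0.75 and -0.74 at weeks 4 and 6.

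At week 2 the largest list difference was in cholesterol synthesis, where 9 of 19 genes were at least 2-fold lower in infected liver and none higher by as much (median -0.97, below all 10000 random lists). Mvd was 4.57-fold lower, Sqle, which makes squalene epoxide, 3.79-fold, Insig1, a sensor of sterol levels, 2.99-fold, Idi1 2.73-fold and Pmvk 2.66-fold. A second Sqle probe was lower by -0.85 on the log2 scale. The same list differed by medians of 0.37 to 0.80 between pairs of uninfected arrays of weeks 2, 4 and 6. Its mean log2 signal was 9.73 in the uninfected array of week 2 against 9.01 to 9.17 in the other uninfected arrays and 8.70 in the infected array of week 2, so part of the difference followed the uninfected array. Fatty acid synthesis genes had a median of -0.27 (0.13 to 0.44 between those uninfected pairs), with the lipid droplet gene Pnpla3 3.87-fold lower and Gpam 2.16-fold lower. Neutrophil genes were again higher (median 0.62, above all random lists), although 2 of 11, S100a8 (2.31-fold) and Ltf (at least 1.63-fold, measured at 2.07-fold), reached a measured 2-fold. Matrix genes had a median of 0.36 (0.24 with bounds), with 3 of 31 at least 2-fold higher. T cell genes had a median of -0.44, with Zap70, a kinase of the T cell receptor, 1.86-fold lower.

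The highest single genes at week 2 were Asns, which makes asparagine and belongs to the amino acid stress response (12.5-fold), Egr1, an immediate early transcription factor (5.84-fold), Elovl3 (4.88-fold), Arrdc3 (4.75-fold), Moxd1 (at least 4.01-fold) and Trat1 (at least 3.82-fold). A second probe of Asns differed by 0.28 on the log2 scale and a second probe of Trat1 by 0.99. In the unfolded protein response list, whose median was -0.08, Chac1 (2.92-fold) and Atf5 (2.01-fold) were also higher. The lowest genes were Acnat2 (7.76-fold lower), Fmr1nb (at least 5.20-fold), Mvd, the beta globin gene Hbb-b2 (4.27-fold), Ppp1r3b, a regulator of glycogen synthesis (4.27-fold), and Pnpla3. Against the mean of the 4 uninfected arrays most of these log2 differences were smaller, at 2.93 for Asns, 1.69 for Egr1, 1.24 for Elovl3, 0.74 for Arrdc3, 1.85 for Moxd1, -1.53 for Acnat2, -1.2 for Fmr1nb, -0.84 for Mvd, -1.04 for Ppp1r3b and -0.90 for Pnpla3. Trat1 (2.45, from 2.56 as measured and not as a bound) and Hbb-b2 (-1.68) moved less. That mean includes the uninfected array of week 2 itself, so part of its deviation remains in these values by construction. Erythroid genes as a list had a median of -0.34 (0.07 to 0.42 between uninfected arrays of weeks 2, 4 and 6). The clock gene Arntl was 3.25-fold lower and Dbp 2.60-fold higher, while the circadian clock list had a median of 0.01. In total 51 genes were at least 2-fold higher and 74 lower. Each pair of uninfected arrays among weeks 2, 4 and 6 differed in more genes, 305 to 890. Such pairs also differ in week, which the 2 arrays of week 2 share. Pairs of infected arrays of weeks 2, 4 and 6 likewise differed in 196 to 201 genes. Each of these infected pairs includes the array of week 4 or 6, which may be a mean of 2 hybridizations and so give lower counts. The lower count at week 2 thus does not say whether infection changed genes.

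At week 4, 447 genes were at least 2-fold higher and 439 lower in infected liver. Much of this count followed the uninfected array of that week. Against the mean of the uninfected arrays of weeks 2 and 6, 53 genes were higher and 99 lower, a comparison chosen after the data were seen. A mean of 2 arrays lowers such counts by itself. Against single uninfected arrays, the infected array differed in 396 genes from week 2 and 165 from week 6. The uninfected array of week 4 differed from them in 449 and 890. Macrophage and Kupffer cell genes were lower, with 6 of 23 at least 2-fold lower and 1 higher (median -0.75, -0.64 with bounds, and -0.24 against weeks 2 and 6), including Lyz2 (5.39-fold, and -1.18 on the log2 scale by a second probe) and Cd53 (2.86-fold). MHC class II genes had a median of -0.48 (-0.29 against weeks 2 and 6), B and plasma cell genes of -0.51 (-0.19 with bounds, and -0.32 against weeks 2 and 6) and T cell genes of -0.46 (-0.05 against weeks 2 and 6). S100a8 and S100a9 were 6.88-fold and 6.16-fold lower, and remained lower by -1.96 and -1.51 on the log2 scale against weeks 2 and 6. The acute phase list had a median of 0.34, which became -0.13 against weeks 2 and 6. Saa2 was 5.70-fold higher against the uninfected array of the week.

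The highest single genes at week 4 were Moxd1 (at least 13.5-fold), Acta1, the actin of skeletal muscle (at least 12.6-fold), Fbxw5 (12.1-fold), Psmc1 (at least 11.5-fold), Scara5 (7.32-fold) and Treh, which splits trehalose (6.84-fold). Acta1 was high together with the muscle genes Atp2a1 and Tnni2, and all of them were also high in the uninfected array of week 1 (see the other observations below). Against weeks 2 and 6 the log2 differences of Moxd1 and Acta1 were 3.70 and 4.51 as measured and not as bounds, although Acta1 lay below background in both references and Moxd1 in that of week 2, whereas Fbxw5 differed by 1.81 there, Psmc1 by 1.76, Treh by 1.15 and Scara5 by 0.31. The lowest were Cyp4a14, a fatty acid hydroxylase under PPAR alpha (15.2-fold lower), Rad51b (11.3-fold), Acot3 (10.2-fold), Serpina7, the thyroxine-binding globulin (9.06-fold), S100a8 and S100a9. Cyp4a14 turned to 0.53 higher on the log2 scale against weeks 2 and 6, and Rad51b (-0.41), Acot3 (-1.12) and Serpina7 (-1.16) were much nearer to 0. The circadian clock list had a median of 0.61 (0.37 against weeks 2 and 6), with Usp2 2.95-fold and Nr1d1 2.72-fold higher, while the other probes differed by 0.55 and -0.17 for Usp2 and by 0.87 and -0.37 for Nr1d1. Gluconeogenesis and fasting had a median of 0.48 (0.22 with bounds), which was 0.09 against weeks 2 and 6, with the glucocorticoid target Fkbp5 3.34-fold higher. Fatty acid synthesis had a median of 0.36, which was 0.02 against weeks 2 and 6, with Acaca 3.0-fold and Fasn 2.20-fold higher and a second Acaca probe at 0.02. Bile acid genes had a median of 0.24 (0.16 with bounds), inside the middle 95% of random lists and 0.09 against weeks 2 and 6, with Cyp8b1, which sets the share of cholic acid, 3.77-fold higher. Male-biased liver genes had a median of 0.28 (0.22 against weeks 2 and 6), with 6 of 14 at least 2-fold higher, and female-biased ones of -0.24 (-0.26 against weeks 2 and 6), both inside the middle 95% against the uninfected array of the week and outside it against weeks 2 and 6, with Acot3 and Cyp2b9 (at least 4.65-fold) lower. Against weeks 2 and 6 the unfolded protein response list went from a median of -0.04 to -0.40, below all random lists, and the cell cycle list from 0.03 to 0.22, beyond the middle 95%. The type 2 response (-0.13), cholesterol synthesis (-0.13) and glutathione (-0.06) lists also lay beyond it only against that reference.

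**Figure D2:**
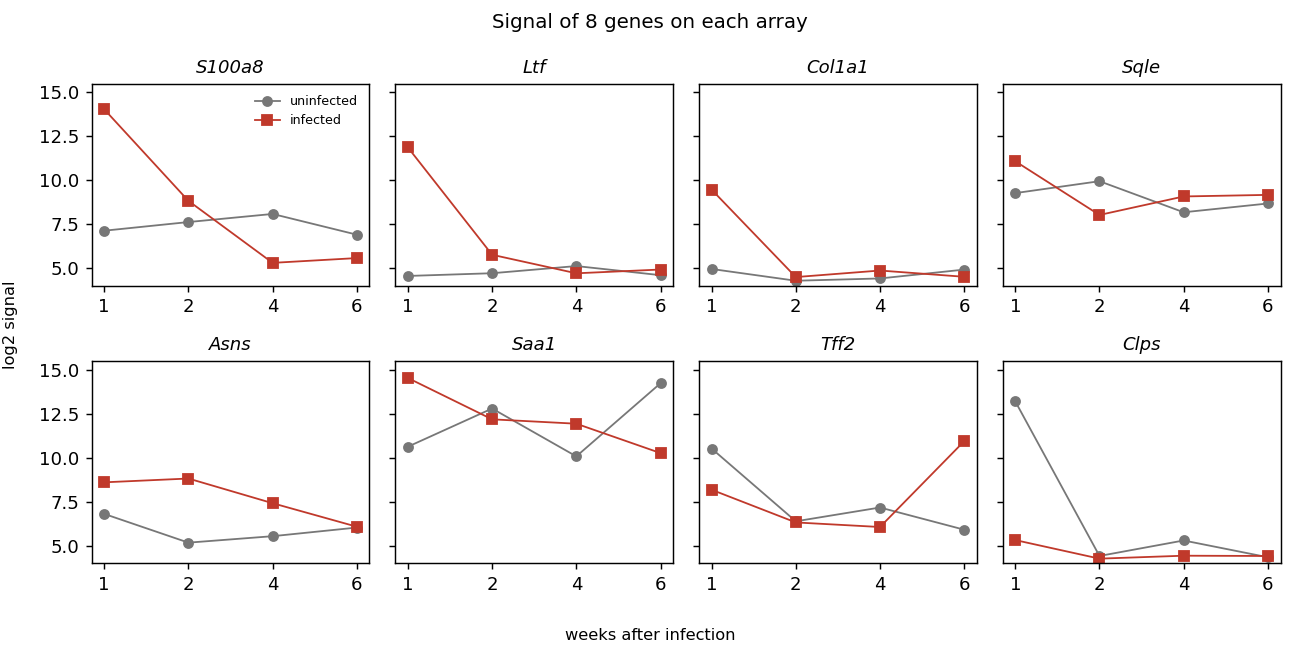
Normalized log2 signal (vertical axis) of 8 genes on each of the 8 arrays by week after infection (horizontal axis, evenly spaced), with infected arrays as red squares, uninfected arrays as grey circles and lines joining arrays of a group. S100a8 and Ltf stand at 14.04 and 11.87 in the infected array of week 1, Clps at 13.21 in the uninfected array of that week, Saa1 at 14.24 in the uninfected array of week 6 and Tff2 at 10.95 in the infected array of week 6.

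At week 6 the highest genes in infected liver were Tff2, a trefoil peptide secreted with mucus (32.8-fold), and Dmbt1, a secreted scavenger receptor of mucosal surfaces and bile ducts (at least 16.7-fold). They were followed by Fbxw5 (at least 8.97-fold), Rad51b (3.04-fold), Gkn3, a peptide of gastric mucous cells (2.90-fold), and Svil (2.71-fold). Against the mean of the 4 uninfected arrays the log2 differences were 3.45 for Tff2, 3.04 for Dmbt1, 1.24 for Gkn3, 1.16 for Svil, 0.84 for Fbxw5 and 0.003 for Rad51b. That mean includes the uninfected array of week 6 itself. Rad51b was thus not higher than the mean of the earlier uninfected arrays. Bile duct genes had a median of 0.37, above all 10000 random lists (0.31 with bounds). The 1 of 16 that was at least 2-fold higher was Tff2 itself. The list of gut and gallbladder epithelium, which holds Dmbt1, had a median of 0.24. Pairs of uninfected arrays of weeks 2, 4 and 6 differed by medians of 0.08 to 0.41 and 0.06 to 0.38 for these 2 lists. Both lay within that spread, which includes differences between weeks. Tff2 and Dmbt1 were also high in the uninfected array of week 1, where pancreas genes were high, with Tff2 at a log2 signal of 10.53 and Dmbt1 10.2-fold above the infected array. Cell cycle genes had a median of 0.26, again above all random lists, with 2 of 27 at least 2-fold higher, of which Mcm5 stood at 2.10-fold. Unfolded protein response genes had a median of 0.22, within the 0.17 to 0.57 between those uninfected pairs, with the chaperone cofactor Creld2 2.13-fold higher.

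Macrophage and Kupffer cell genes were lower at week 6, with 8 of 23 at least 2-fold lower and none higher by as much (median -0.74, below all 10000 random lists, and -0.51 with bounds). The same list differed by medians of 0.06 to 0.39 between pairs of uninfected arrays of weeks 2, 4 and 6. Lyz2 was 2.47-fold lower (-0.42 on the log2 scale by a second probe) and Cd53 1.72-fold lower, while Gpnmb was at least 1.39-fold higher. MHC class II genes had a median of -0.39, with Cd74 1.78-fold lower. Acute phase genes had a median of -0.30, within the 0.07 to 0.34 between those pairs, with Saa2 36.3-fold, Saa3 17.9-fold, Saa1 15.7-fold and Lcn2 3.45-fold lower. Mt2, a metallothionein, was 4.55-fold lower and Pstpip2, a gene of myeloid cells, 7.18-fold lower. For Saa1 the difference followed the uninfected array, whose log2 signal of 14.24 compared with 10.63, 12.81 and 10.08 in the other uninfected arrays. Against the mean of the 4 uninfected arrays all 6 genes were less far below, with log2 differences of -1.67 for Saa1, -2.29 for Saa2, -1.85 for Saa3, -0.53 for Lcn2, -1.46 for Mt2 and -1.71 for Pstpip2. That mean includes the uninfected array of week 6 itself, so part of its deviation remains in these values by construction. In total 30 genes were at least 2-fold higher and 40 lower, fewer than between any pair of uninfected arrays, although those pairs also differ in week. The infected array of week 6 may also be a mean of 2 hybridizations, which would lower its counts.

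**Figure D3:**
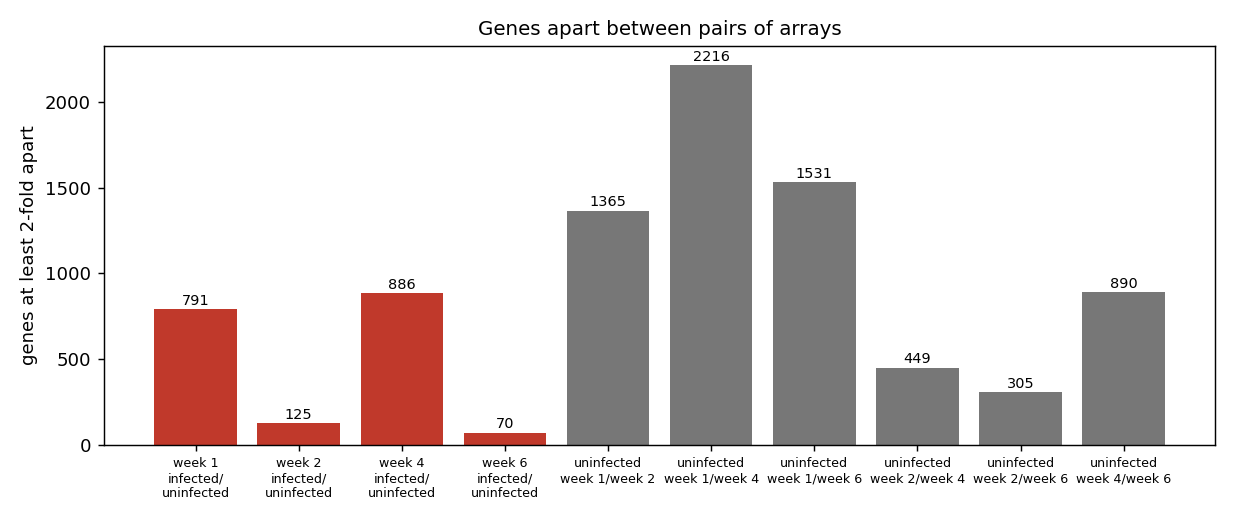
Number of genes at least 2-fold apart (vertical axis) between the infected and uninfected array of each week (red bars) and between each pair of uninfected arrays (grey bars). The counts for weeks 2 and 6, 125 and 70, lie below every uninfected pair, and the count for week 4, 886, lies close to that between the uninfected arrays of weeks 4 and 6, 890. Uninfected pairs also differ in week, which the arrays behind each red bar share. The infected arrays of weeks 4 and 6 may be means of 2 hybridizations, which would lower their counts.

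The second comparison asks which genes differed with infection in the same way over all 4 weeks, with the week in the fit. No gene passed in limma at an adjusted p under 0.05, where 599 of 10380 genes had an unadjusted p under 0.05 and about 519 would by chance. The smallest adjusted p was 0.76. The 10 genes with the smallest p among those higher in infected liver, none past the threshold, were Ttyh3, Tchp, Acap3, Bcl3, Map11, Med12, C2cd5, Smtn, Myadm and Sox9, each higher at 4 of 4 weeks. Sox9, a transcription factor of bile duct cells and their progenitors, was higher by 0.82 on the log2 scale (SD 0.42 over 4 weeks), and Bcl3, a partner of NF-kappa B, by 0.98 (SD 0.51). The 10 with the smallest p among the lower genes were Acot13, Pstpip2, Sucnr1, Csrp3, Fam13a, Nrg4, Igfbp1, Hacl1, Chac2 and Acot4, each lower at 4 of 4 weeks. Pstpip2 had a mean log2 difference of -2.07 (SD 1.09), Acot4, a peroxisomal thioesterase, of -1.11 (SD 0.71), Sucnr1, the succinate receptor, of -0.93 (SD 0.33) and Acot13, a thioesterase of fatty acid metabolism, of -0.83 (SD 0.19). A second probe of Hacl1 showed almost no change, at -0.15 to 0.05 over the weeks. The fit was also run on data simulated from each gene's residual SD, taken as its true SD, with errors independent between genes. There it recovered 53 of 100 genes changed 2-fold and 90 of 100 changed 4-fold. Errors on these arrays may be shared between genes, so these shares need not hold for them.

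Among the 34 gene lists, 7 passed limma's camera test across weeks with its preset correlation of 0.01, and none did with an estimated correlation or with fry. Matrix genes rose (adjusted p = 3.6e-06, and p = 0.24 with an estimated correlation), with 25 of 31 genes higher on the mean of 4 weeks. Cell cycle genes rose (adjusted p = 0.00047, and p = 0.30 with an estimated correlation), as did neutrophil genes (adjusted p = 0.0023, and p = 0.33 with an estimated correlation), bile duct genes (adjusted p = 0.0076, and p = 0.15 with an estimated correlation), immediate early genes (adjusted p = 0.0082, and p = 0.21 with an estimated correlation) and acute phase genes (adjusted p = 0.026, and p = 0.42 with an estimated correlation). Pancreas genes fell (adjusted p = 6.8e-06, and p = 0.28 with an estimated correlation). Fatty acid oxidation genes did not pass (adjusted p = 0.052), with 13 of 22 lower on the mean. All 7 calls ended when week 1 was left out, and the neutrophil list then pointed down with an adjusted p of 0.79. The macrophage list (adjusted p = 4.5e-07, mean -0.44) and the MHC class II list (adjusted p = 0.022) then fell and the clock list rose (adjusted p = 0.023), but with an estimated correlation, a test added after the data were seen, no list passed without week 1 (adjusted p = 0.81 for each of these 3). Mean and median differences across weeks had opposite signs for T cells, macrophages, glutathione and oxidative stress defence and male-biased genes, none of them past the threshold. No member of any list passed over all genes. Adjusted over the list alone, 2 of 10 female-biased genes and 1 of 15 genes of gluconeogenesis and fasting passed, and no member of any other list. These were Acot3 and Cyp4a10, and Igfbp1, all lower in infected liver on the mean.

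Against the uninfected array of the same week, no median beyond the middle 95% of random lists was seen at any week for NK and cytotoxic cells, for eosinophils, mast cells and basophils, for glutathione and oxidative stress defence, for hepatocyte secretory proteins or for adipose genes. The medians of the adipose list were -0.10, 0.13, 0.14 and 0.14 at weeks 1, 2, 4 and 6.

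The third comparison asks whether the difference between infected and uninfected liver was another late, at weeks 4 and 6, than early, at weeks 1 and 2. No gene passed in limma, with 351 of 10380 at an unadjusted p under 0.05 and a smallest adjusted p of 0.98. In data simulated in the same way this fit recovered 0 of 100 genes at 2-fold and 0 of 100 at 4-fold. The lack of calls thus says little about changes of that size. Without week 2, 47 genes passed as higher late and 221 as lower late, while 0 or 1 gene passed without any other week, each fit having 1 remaining degree of freedom. The genes with the smallest p, none past the threshold with all weeks, were lower late for Trat1, Egr1, Psat1, which makes serine, Dock10, Mmp17, Pf4, which encodes a platelet chemokine, Fcna, Vstm4, Angpt2 and Lyve1, a marker of liver sinusoids and lymph vessels. They were higher late for Gstt3, Mfsd2a, G6pc, Pcdhgb4, Tedc2, Fbxw5, Ppp1r3b, Khdrbs3, Ppp1r3c and Aacs. G6pc was -1.76 and -1.33 on the log2 scale at weeks 1 and 2 and 0.81 and -0.19 at weeks 4 and 6. Egr1 stood at 2.54 and 2.55 early and at 0.77 and 0.55 late. A second Dock10 probe went the other way, at -0.61 and -0.25 early and 0.06 and 0.13 late. A second Trat1 probe was also lower late, at 1.12 and 0.99 early and 0.07 and 0.30 late. Of the gene lists, 20 of 34 passed camera for this contrast with the preset correlation, a test added after the data were seen, and none passed with an estimated correlation.

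The last comparison asks what changed with week in uninfected mice, where age and array order move together. In simulated data this fit recovered 95 of 100 genes seeded with 1 log2 unit per week, a steep slope. No gene passed in limma for the slope, with 590 of 10380 at an unadjusted p under 0.05 and a smallest adjusted p of 0.71. The smallest p belonged to Nr1d2, a repressor of the molecular clock, at -0.52 log2 units per week (SE 0.07, unadjusted p = 0.00012 in limma over 8 arrays). The other lower genes of smallest p, not past the threshold, were Nop56, Avpr2, Cldnd2, Mtrf1, Olfr916, Sp8, Arfgap2, Thrsp and Prl8a9. The higher ones were Csta2, Csrnp1, Nrip1, Fam13a, Evl, Myo10, Cadps2, Zfp979, Cblb and Gata6, with slopes of 0.28 to 0.50 per week. The arrays of week 1 had another background treatment from the rest, so the slope carries that difference too.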

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

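The tests of the 3 patterns weighed here were all chosen after the values were seen, while the counts of other splits were planned before.

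Lists were checked for an array far from the other 3 of its group, by the gap to the nearest array over the range of the 4. Of 70 such groups 7 passed the critical value of 0.83. That value passes about 1 in 20 groups of 4 independent replicates. The 4 arrays of a group are of different weeks here and the lists are not independent, so this rate does not measure chance. The infected array of week 1 was the highest of the infected arrays for interferon gamma genes (ratio 0.965), eosinophil, mast cell and basophil genes (0.944), type 2 response genes (0.934), oncofetal and regeneration genes (0.892) and immediate early genes (0.866). The uninfected array of week 1 was the highest of the uninfected arrays for pancreas genes (0.959). The uninfected array of week 4 was the lowest for fatty acid synthesis genes (0.858).

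Higher neutrophil, matrix and cell cycle genes in infected liver at week 1 came with pancreas RNA in the uninfected sample of that week. Dilution of its liver RNA by pancreas would raise markers of cell types other than pancreas in the infected array alike. The neutrophil median exceeded the endothelial median by 4.98, more than the spread within either list. Pancreas tissue can bring endothelial RNA of its own, however. Hepatocyte secretory genes, which dilution would also raise, had a median of -0.08 (SD 0.41 between members), against 5.10 for neutrophil genes. This argues against dilution as the whole cause for the neutrophil list. The matrix and cell cycle lists were not compared in this way. The missing background subtraction at week 1 applies to both arrays, and under 6 other background and scaling settings the neutrophil median was 3.51 to 4.68 and the lowest median of the neutrophil, matrix and cell cycle lists was 0.91, which argues against that treatment as the whole cause. A response to migrating young flukes and a difference between these livers with no link to the infection cannot be told apart, since week 1 has 1 infected array. Week 1 is thus a hypothesis for replication, not an established response.

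The week 4 differences may come from the uninfected array of that week. It differed at least 2-fold from the mean of the uninfected arrays of weeks 2 and 6 in 474 genes, against 156 for the infected array of week 4 (counted among genes detected on that array or those of weeks 2 and 6, and 53 higher and 99 lower among genes detected at week 4), and of the 886 genes apart at week 4 the infected array was the nearer to that mean in 675. Between single arrays the contrast was small against uninfected week 2 (449 genes for the uninfected array and 396 for the infected). It was large against uninfected week 6 (890 and 165). The infected array of week 4 may be a mean of 2 hybridizations, which would lower its own count. A trend with genomic gene length does not account for the pattern, because 786 of the 886 genes stayed at least 2-fold apart after it was removed. Whether the uninfected liver itself or its RNA was unusual stays open, and a change with infection in the genes that still differed from that mean, such as Moxd1, was not tested.

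The differences of weeks 2 and 4 correlated across genes (r = 0.35), where genes are not independent replicates, while the other pairs of weeks gave -0.08 to 0.09. A candidate explanation is a shared deviation of the uninfected arrays. With different week 6 arrays as references, so that no array was shared, deviations of the uninfected arrays of weeks 2 and 4 correlated at 0.34 and 0.44 (covariance 0.09 and 0.11), and those of the infected arrays at 0.18 and 0.20 (covariance 0.03 in both). A length trend is argued against, since r was 0.34 after its removal. The 2 week 6 references share deviations of their own week (r = 0.41 across genes), which adds covariance to all 4 values. The values of the infected arrays may come from this alone, so they can neither show nor exclude a common response to infection at both weeks.

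For infection across weeks, only 8 splits keep 1 array of each group at every week, too few for a share under 0.05. The real split gave 599 genes at an unadjusted p under 0.05 and the highest other split 733, with 2 of 8 splits, the real one included, at or above the real count. For the gene lists the real split gave 7 lists past the threshold and the highest other 21, and all 8 splits gave at least 7. With the week left out, 23 of 35 splits of the 8 arrays gave at least the 171 genes of the real one, so chance cannot be excluded there. The highest other split gave 1550, many times the real count, which points to structure by week: the splits with most genes kept both arrays of week 1 on the same side.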

How the results depend on the processing

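The saddle-point background, the reference of uninfected weeks 2 and 6, the removal of members of the pancreas, gut and adipose lists and the estimated correlation without week 1 were chosen after the data were seen. Counts of 0 genes across weeks and for the slope stayed at 0 under every alternative, with 171 to 1127 and 169 to 1520 genes at an unadjusted p under 0.05 in limma. In the fit with no replicate block (no pairing by week), 0 genes were higher and 0 lower, and 6 lists passed. The late contrast stayed at 0 except when a week was left out, where 0 to 47 genes were higher and 0 to 221 lower, the most without week 2, and the cause was not tested. The number of lists past the threshold across weeks was 4 with genes detected on all 8 arrays, 0 with an estimated correlation (also 0 without week 1) and 0 with fry, and 3 to 17 when a week was left out. With a week left out the mean of the neutrophil list was -0.12 to 1.71, the lowest without week 1.

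Counts at 2-fold (higher, then lower) were 587 and 204 at week 1, 51 and 74 at week 2, 447 and 439 at week 4 and 30 and 40 at week 6. An offset of 50, which shrinks folds by construction, gave 373 and 127, 24 and 38, 266 and 262, and 10 and 16. At 1.5-fold they were 1158 and 887, 516 and 449, 1498 and 1387, and 295 and 315. With no normexp correction they were 24 and 40 at week 2, 282 and 283 at week 4 and 11 and 17 at week 6. The deposited value table gave 66 lower at week 1, 26 lower at week 2, 285 higher at week 4 and 12 and 22 at week 6. Genes detected on all 8 arrays, a smaller set, gave 379 higher at week 1 and 16 and 26 at week 6. The saddle-point background gave 29 and 49 at week 2 and 15 and 25 at week 6. Against the mean of the 4 uninfected arrays, 644 were lower at week 1, 48 lower at week 2, 85 and 147 differed at week 4 and 50 were higher at week 6. Against uninfected weeks 2 and 6, 53 were higher and 99 lower at week 4, and Cyp4a14 turned to 0.53. The deposited value table has minima of 30.3 to 66.3 on its arrays, and such a floor shrinks folds of dim genes as a larger offset does. Its counts are therefore no independent check. How much of its moves came from this was not tested. Except for the offset and the detection filter, the cause of the other moves was not tested. The median difference over all genes moved beyond 0.1 only with same-median scaling at week 1 (-0.13) and in the deposited value table at weeks 1 and 2 (0.13 and 0.14). Counts of lists beyond the middle 95% at each week stayed within 1.5 times. Where a gene lay below background on one array, its fold is only a lower bound, so the size of such differences is not measured.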

Other observations

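The test of probe changes below was planned before its result was seen, and the tests of neighbouring tissue and the choice of other genes named here came after.

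Acta1, Atp2a1 and Tnni2, picked after the values were seen and part of no tested list, were high on 2 arrays that share neither group nor week. Acta1 reached log2 signals of 8.92 in the uninfected array of week 1 and 8.74 in the infected array of week 4, against 4.19 to 4.47 in the other 6. Atp2a1, the calcium pump of fast muscle, stood at 7.29 and 7.08 in these 2 arrays and at 4.35 to 4.67 in the others, and Tnni2, a fast muscle troponin, at 7.73 and 7.17 against 4.30 to 4.95. Some single genes were on or off between arrays without regard to group. Fbxw5 stood at 8.17 to 9.78 on 5 arrays and at 4.69 to 5.37 on the other 3, and Psmc1 at 7.43 to 8.76 on 4 arrays and 4.59 to 5.22 on 4. Each of the 2 had a single kept probe.

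Elane and Prtn3, members of the neutrophil list picked here after the values were seen, were high in infected liver at week 1. Elane stood at a log2 signal of 9.18 there against 4.71 in the uninfected array and Prtn3 at 9.37 against 4.60, while both lay between 4.37 and 5.93 on the 6 arrays of the later weeks. Uhrf1, a gene of dividing cells, stood at 9.36 in the infected array of week 1 against 5.94 in the uninfected one, and at 7.87 against 6.80 at week 6. Ccnd1, which encodes cyclin D1, was higher by 1.23 on the log2 scale at week 6. Further Kupffer cell genes of the macrophage list were lower at week 6 too: Vsig4 at 9.33 against 10.61, Adgre1 at 8.19 against 9.46, Clec4f at 7.89 against 8.63 and Timd4 at 7.09 against 7.88.

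A set of 50 probes was detected on none of the week 1 arrays and on all 6 later arrays, with a shift of over 2 log2 units, and 11 probes showed the opposite. No other week had such probes. Hsp90aa1 stood at a log2 signal of 4.49 on average at week 1 and at 8.35 later, Fgb, which encodes a chain of fibrinogen, at 4.80 and 8.60, and Fabp1 at 4.43 and 7.45. The hypothesis was that the probes, not the RNA, had changed, as on another version of the array, in which case other probes of the same genes would not be lower at week 1. The 16 other kept probes of these genes had a median shift of 0.45, against -2.57 for the 50, and 1 of the 16 lay below -1. This is consistent with a change of probes between week 1 and the later weeks. Both arrays of week 1 share it, so it would not create differences within the week, but it can hide them. Hsp90aa1, Fgb and Fabp1 had no other kept probe, so a difference of theirs at week 1 could not be seen. Such genes entered the fits with background signal on both arrays of week 1. Fits without the week and the slope in uninfected mice carry the shift itself.

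Tff2 and Dmbt1, the highest genes of infected liver at week 6, are also made by stomach and gut. Pancreas in the sample would raise its list, but the pancreas list had a median difference of 0.064 and no member above 0.60, which argues against it. Intestine is left open. The gut and gallbladder list had a median of 0.24, at the 98.3rd percentile of random lists, with 2 of 10 genes at least 2-fold higher and an SD of 1.39 between members. Dmbt1 is itself 1 of these 2 genes, at 4.51 as measured, and widens that SD. The SD without Dmbt1 was not computed, so this list cannot decide on intestine. Stomach and gallbladder tissue remain possible, since no list covered the stomach and few genes of the gut list are specific to the gallbladder. A mucous change of the bile ducts is a hypothesis that these arrays cannot test.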
